A study of Mus musculus with 6 samples.

How the data were processed

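Bulk RNA was measured in 6 mouse libraries, 3 of bone marrow LSK cells and 3 of ESC-derived Lin-negative, Sca-1-positive, c-Kit-negative cells, each made from 2000 sorted cells. Per the labels' protocols, cDNA was made with the SMART-Seq v4 kit, which primes on poly(A) tails and does not mark strand, and libraries were built with the Nextera XT transposase kit and sequenced on an Illumina instrument. The submitters' processing notes name HISAT, StringTie and the mouse build mm10, with no versions or roles. Settings, annotation and the program that wrote the count table are not given in the sources used here.

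The deposited values are estimated counts per Ensembl gene ID, written as whole numbers and not normalized. In each library 4 was more frequent than 3 or 5, and 40.1 to 47.2% of the values from 1 to 20 were divisible by 4. A sequenced fragment was thus often worth about 4 counts, so counts overstate the number of fragments. The floor used for genes at 0 is therefore 12 counts over the 3 libraries of a group, which is 3 fragments at 4 counts each. Floors and counting intervals cover counting error only, since these reads carry no molecular identifiers. The header of the table holds the names of its 6 value columns in a single field. The columns were assigned from the order of the names in that field, and the Kit counts per library, 2, 4 and 6 in the ESC-derived columns and 2081 to 2550 in the LSK columns, go with the c-Kit gates. The table has 55401 gene IDs, of which 55141 matched GENCODE M21, an annotation of the same genome build as mm10, and 260 did not. Symbols, positions and biotypes come from that annotation. Where several IDs share a symbol, the ID with the most counts was used.

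Total counts per library ran from 41580006 to 49269286. The deposited values were used as they stand. Genes were filtered with filterByExpr, which left 16211, scaled with TMM and tested with the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The contrast was ESC-derived minus LSK, with no replicate block. CPM values come from edgeR's cpm function on the TMM-scaled libraries, with the SD over 3 libraries. The SE of a log2 fold change was taken from the fold change and its F statistic. A gene whose total in a group was at or under the floor has a ratio of sums with an exact 95% counting interval or, at 0, a lower bound against the floor. The 33 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists of programs and cell types with at least 3 tested members were tested with camera (limma 3.58.1, inter-gene correlation preset to 0.01), which left 29. Numbers of genes detected at 1 CPM or more were compared by an exact two-sided permutation test over the 10 splits of the 6 libraries.

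The rule for named genes took 10 fixed genes (Kit, Ly6a, Ptprc, Cdh5, Cd34, Flt3, Hoxa9, Runx1, Mecom and Il7r), the 8 largest rises and the 8 largest falls among genes past the threshold, with no overlap between the groups, a mean of at least 50 CPM in the higher group and an assigned symbol other than a receptor segment, up to 2 higher and 2 lower members of each list by adjusted p, and the sex-linked genes. For a list with no call the rule took the members with the highest mean CPM. Other genes are named as chosen after their values were seen. The lists comprised genes of haematopoietic stem cells, Hox and TALE cofactors, early lymphoid progenitors, B cells, plasma cells, T cells, NK and cytotoxic lymphocytes, ILC2 and type 2 lymphocytes, neutrophils, monocytes and macrophages, dendritic cells, erythroid cells, embryonic globins, megakaryocytes, mast cells with basophils and eosinophils, endothelium, stroma, pluripotency, fetal haematopoiesis, S phase, G2/M, cell cycle inhibitors, interferon response, MHC class I, MHC class II, immediate early and stress response, NF-kB and TNF response, glycolysis, oxidative phosphorylation, ribosome biogenesis, lineage gate antigens, sort genes and sex-linked genes.

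The alternatives were the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, RLE and upper quartile scaling, library totals only, no low-count filter and a stricter one of 50 counts in 3 libraries, a test against a 2-fold change, counts thinned to the smallest library, the replicate number as a block, and each library left out in turn. For lists they were an estimated correlation, the fry test and rank-based camera. Division of the values by 4, libraries without immunoglobulin genes, and libraries without receptor and lymphocyte list genes were chosen after seeing the data. The fit was tested on simulated counts for the ESC-derived minus LSK comparison, with the real means, library sizes and spread, 15507 genes in the fit and 50 changed genes per fold size. It recovered 0% of 2-fold, 58% of 4-fold, 60% of 8-fold and 78% of 16-fold changes and called 6 unchanged genes. Far fewer genes changed there than the 4861 called in the data, which makes the adjustment stricter. These shares therefore do not give the recovery in the real fit. In a second simulation over 15542 genes, camera called 10 of 10 lists of 20 members shifted 2-fold and 0 of 10 unshifted lists. Genes were drawn independently there, so it cannot show how often camera calls unshifted lists with correlated members. In the data the estimated correlation reached 0.35, in the MHC class II list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads that fall on exons of genes on opposite strands cannot be assigned to one of them, and counts of receptor segments, H2 genes and other near-identical copies can be split between copies.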

Results

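Gene expression was measured in 6 bulk libraries of 2000 sorted mouse bone marrow cells each, 3 in each of 2 groups. The LSK group held cells labelled Lin-negative, Sca-1-positive and c-Kit-positive, the marrow fraction that contains haematopoietic stem and multipotent progenitor cells, from C57BL/6 mice aged 6 to 8 weeks. The ESC-derived group held cells labelled Lin-negative, Sca-1-positive and c-Kit-negative, sorted from the marrow of primary recipients into which CD144-positive cells made from embryonic stem cells had been transplanted. CD144, the product of Cdh5, is an adhesion molecule of endothelial cells. Total estimated counts were 42763411, 41580006 and 44481252 in LSK replicates 1 to 3 and 46299936, 47977215 and 49269286 in ESC-derived replicates 1 to 3.

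The comparison asked how the ESC-derived c-Kit-negative cells differed from LSK cells of adult marrow. T cell and cytotoxic lymphocyte transcripts were high in the ESC-derived libraries, and stem cell, Hox and B cell transcripts were low. Of 26 T cell genes tested, 25 rose and 0 fell. Cd8a, a co-receptor of cytotoxic T cells, averaged 1177 ± 85.4 CPM in ESC-derived cells and 2.52 ± 0.504 CPM in LSK cells (SD, n = 3 libraries per group here and throughout), a log2 fold change of 8.87 ± 0.21 (SE). Of 40 haematopoietic stem cell genes tested, 23 fell, 3 rose and 14 did not pass. Hoxa9, a homeobox gene of stem and progenitor cells, averaged 62.6 ± 6.37 CPM in LSK cells and had 0 counts in the ESC-derived libraries, at least 687-fold lower against the floor of 12 counts over a group. In all, 4861 of 16211 tested genes differed at an adjusted p of 0.05 (edgeR quasi-likelihood test), 2395 higher and 2466 lower in ESC-derived cells, and 3817 of them by 2-fold or more. LSK replicate 2 lay close to a mixture of LSK replicates 1 and 3, as set out below. If it is one, the LSK spread and the p-values are too small. Without LSK replicate 2, 2716 genes differed, 1466 higher and 1250 lower, against 3819 and 3905 genes without LSK replicates 1 and 3.

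Among the genes of the sort, Kit, the receptor behind the c-Kit gate (ENSMUSG00000005672, mm10 chromosome 5, 75574916 to 75656722, plus strand), averaged 48.7 ± 6.38 CPM in LSK cells and 0.0896 ± 0.0398 CPM in ESC-derived cells. The ESC-derived total of 12 counts gave a ratio of 533 (95% counting interval 182 to 2586). Ly6a, which encodes Sca-1 (chromosome 15, 74994877 to 74998031, minus strand), rose by a log2 fold change of 1.30 ± 0.23, from 288 ± 39.7 to 711 ± 205 CPM. Ptprc, which encodes the pan-leukocyte antigen CD45, rose by 1.75 ± 0.12. Cdh5 had 8 counts over the LSK libraries and 0 over the ESC-derived libraries, both under the floor. Cd34, a surface antigen of progenitors, averaged 592 ± 22.6 CPM in LSK cells and 0.503 ± 0.791 CPM in ESC-derived cells (log2 fold change -10.14 ± 1.17). ESC-derived replicate 3 held 67 of the 71 ESC-derived Cd34 counts, and without it the fitted log2 fold change was -13.52. Flt3, a cytokine receptor of multipotent progenitors, averaged 924 ± 73.4 and 0.584 ± 1.01 CPM (-10.57 ± 1.42) in LSK and ESC-derived cells. All 83 ESC-derived Flt3 counts were in replicate 3, and replicates 1 and 2 had 0. Mecom, a stem cell transcription factor, averaged 17.3 ± 5.92 CPM in LSK cells and had 5 counts in ESC-derived cells, all in replicate 3, a ratio of 458 (counting interval 103 to 22690). Il7r, the interleukin-7 receptor, rose by 1.63 ± 0.25. Runx1, a transcription factor of blood development, averaged 101 ± 22.1 CPM in LSK and 71.3 ± 5.11 CPM in ESC-derived cells and did not pass (log2 fold change -0.50 ± 0.18, edgeR adjusted p = 0.087, range over 19 alternatives 0.0142 to 1). Runx1 passed, as lower in ESC-derived cells, with the DESeq2 Wald test and with library totals only. Of the 3 sort genes tested, 2 rose and 1 fell. All 3 passed adjusted over the list alone.

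**Figure D1:**
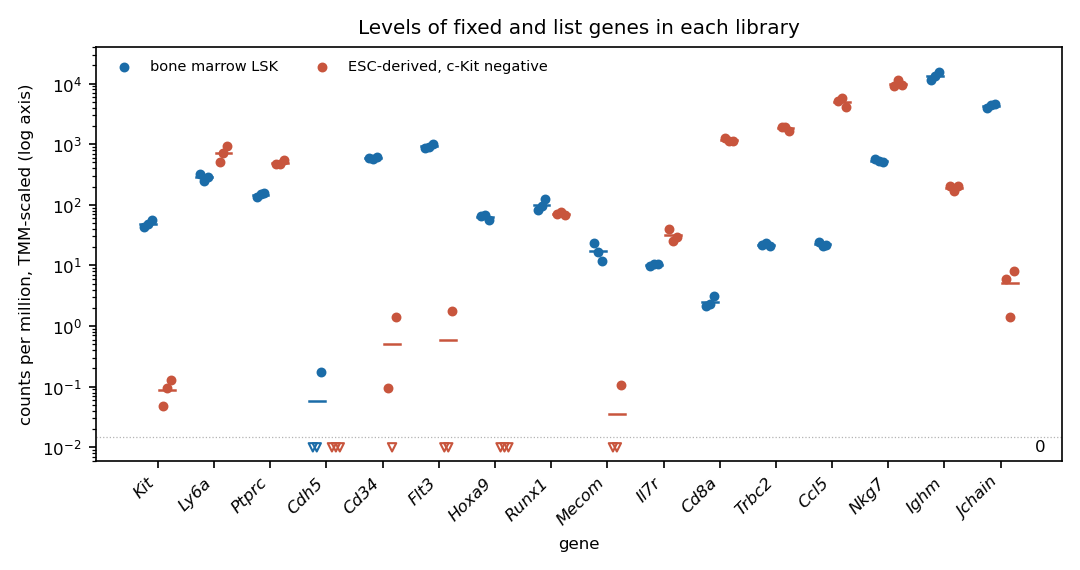
CPM (log axis) of 16 genes in each library, with LSK libraries in blue, ESC-derived libraries in red, lines for group means and open triangles for libraries at 0. Cd8a averaged 2.52 CPM in LSK and 1177 CPM in ESC-derived cells, and Kit averaged 48.7 and 0.0896 CPM.

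Lymphocyte genes formed the groups with the largest shifts upward. Camera p-values below use a preset correlation of 0.01, each range is over 18 alternatives, and the upper end of a range comes from an estimated correlation unless another setting is named. The T cell list (camera adjusted p = 1.3e-98, range 1.23e-103 to 0.000527) had a median log2 fold change of 5.43. Adjusted over the list alone, 25 members rose and 0 fell. Trbc2, a constant segment of the T cell receptor beta chain (chromosome 6, 41546730 to 41548352, plus strand), rose by 6.39 ± 0.13, from 22 ± 1.35 to 1838 ± 144 CPM. Reads of Trbc2 can be split with its near-identical copy Trbc1. Of 21 NK and cytotoxic lymphocyte genes, 18 rose, 1 fell and 2 did not pass, and adjusted over the list alone the counts were 18 and 1 (camera adjusted p = 5.3e-40, range 4.19e-43 to 0.00178). Ccl5, a chemokine of cytotoxic lymphocytes, rose by 7.81 ± 0.19, and Nkg7, a gene of cytotoxic granules, rose by 4.22 ± 0.12 to 9972 ± 1111 CPM, while Ccl4, another chemokine, fell by 0.58 ± 0.09 on the log2 scale. Of 15 ILC2 and type 2 lymphocyte genes, 8 rose, 2 fell and 5 did not pass, likewise adjusted over the list alone (camera adjusted p = 5.9e-10, range 4.08e-11 to 0.0172). Its members Id2, a regulator shared by T, NK and innate lymphoid cells (5.43 ± 0.12), and Icos, a co-stimulatory receptor also found on T cells (3.83 ± 0.16), rose, and Hes1, a Notch target, fell (-5.86 ± 1.24, and -8.80 without ESC-derived replicate 2, which held 143 of its 157 ESC-derived counts). Without LSK replicate 2, 1 member of this list fell. Of 14 MHC class I antigen presentation genes, 12 rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 7.1e-11, range 4.13e-13 to 0.0491). Nlrc5, the transactivator of MHC class I genes, rose by 2.45 ± 0.14. Of 9 lineage gate antigens tested, 7 rose and 0 fell over all genes tested, and 7 rose and 1 fell adjusted over the list alone. Besides Cd8a they included Cd3e, a chain of the T cell receptor complex (6.48 ± 0.20), Cd4 (2.24 ± 0.29, 33.5 ± 7.25 CPM) and Cd5 (3.28 ± 0.26). These transcript levels run against a Lin-negative label if the gate held antibodies to CD3, CD4, CD5 or CD8, and the antibodies are not given in the sources used here. Without ESC-derived replicate 1, 1 lineage antigen fell. T cell receptor genes held 0.66 to 0.686% of counts in the ESC-derived libraries and 0.007 to 0.009% in the LSK libraries.

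Haematopoietic stem cell and Hox genes shifted down, and the early lymphoid progenitor list did not pass. The 40 stem cell genes had a median log2 fold change of -4.35, and adjusted over the list alone 29 fell and 3 rose (camera adjusted p = 8e-12, range 3.69e-19 to 0.0124). Meis1, a cofactor of Hox proteins, fell by 8.40 ± 0.40 on the log2 scale, from 46.9 ± 12.6 to 0.135 ± 0.0373 CPM. The members that rose included Gata3, a transcription factor of T cells as well (3.81 ± 0.23), and Ltb, a cytokine also made by lymphocytes (2.06 ± 0.13). Of 15 Hox and TALE cofactor genes tested, 10 fell, 2 rose and 3 did not pass, and adjusted over the list alone 11 fell and 2 rose (camera adjusted p = 1.1e-07, range 1e-07 to 0.0497). Their median was -8.40 as fitted and -4.11 with the 7 members at 0 in a group set to their bound. Pknox1 rose by 1.27 ± 0.22. The rises in this list numbered 1 without any one of LSK replicates 1 and 2 and ESC-derived replicates 1, 2 and 3. Of 19 early lymphoid progenitor genes, 10 fell and 4 rose, likewise adjusted over the list alone, and the list did not pass (camera adjusted p = 0.4, range 0.00606 with fry to 0.507 with the stricter filter). It passed with fry and without ESC-derived replicate 2 or 3. Dntt, which adds bases at receptor junctions, averaged 275 ± 23.3 CPM in LSK cells and 0.173 ± 0.222 CPM in ESC-derived cells (-10.56 ± 0.77, and -12.42 without ESC-derived replicate 3), while Ikzf3, a lymphoid transcription factor, rose by 4.79 ± 0.19.

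B cell, plasma cell and MHC class II genes shifted down at the preset correlation, and of these the B cell call held with an estimated one. Immunoglobulin genes held 7.54, 8.50 and 9.48% of counts in the LSK libraries and 0.025, 0.019 and 0.037% in the ESC-derived libraries. Class-switched constant genes reached 31.9 to 34.8% of the Ighm counts in the LSK libraries. Part of this RNA may come from antibody-secreting cells, as described below. The falls in this paragraph thus do not by themselves show a loss of B lineage transcripts in ESC-derived cells. Of 24 B cell genes, 16 fell and 0 rose, and adjusted over the list alone 19 fell (camera adjusted p = 5.6e-14, range 1.58e-16 to 0.0303). Ighm, the IgM heavy chain (chromosome 12, 113418558 to 113422730, minus strand), averaged 13466 ± 2087 CPM in LSK cells and 193 ± 23.2 CPM in ESC-derived cells (-6.13 ± 0.18), and Cd79a, a chain of the B cell receptor, averaged 228 ± 3.61 and 2.36 ± 0.925 CPM (-6.59 ± 0.35). Of 11 plasma cell genes, 8 fell and 1 rose, and adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 0.00029, lowest of the alternatives 1.01e-08, adjusted p = 0.168 with an estimated correlation). Jchain, which joins secreted IgM and IgA, averaged 4289 ± 314 CPM in LSK cells and 5.16 ± 3.40 CPM in ESC-derived cells (-9.70 ± 0.74). The rise, of Prdm1, was lost without any one of LSK replicates 1 and 2 and ESC-derived replicates 2 and 3, each leaving 0. Of 10 MHC class II genes, 9 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 4.3e-12, lowest 2.4e-14, adjusted p = 0.0754 with an estimated correlation). H2-Ab1 fell by 4.42 ± 0.21 and Cd74, the invariant chain, by 3.54 ± 0.21 on the log2 scale. Of 19 dendritic cell genes, 11 fell, 3 rose and 5 did not pass, likewise adjusted over the list alone (camera adjusted p = 0.044, lowest 0.000284 with fry, adjusted p = 0.168 with an estimated correlation). The dendritic cell call was also lost with library totals only, with the stricter filter and with values divided by 4. Runx2, also a bone gene, fell by 1.59 ± 0.24 on the log2 scale. The dendritic cell falls numbered 7, 5 and 7 without LSK replicates 1, 2 and 3, and the rises 1 without LSK replicate 2.

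Genes of other blood lineages moved both ways. Of 19 neutrophil and granule genes, 11 rose, 3 fell and 5 did not pass, and adjusted over the list alone 12 rose and 4 fell (camera adjusted p = 0.00039, lowest 0.000101, adjusted p = 0.279 with an estimated correlation). Camp (3.75 ± 0.26) and Ngp (3.04 ± 0.22), genes of neutrophil granules, rose, and Csf3r, the receptor for the neutrophil growth factor G-CSF, fell by 5.90 ± 0.67 on the log2 scale (-6.75 without ESC-derived replicate 1). Without ESC-derived replicate 3, 5 members fell. Of 21 monocyte and macrophage genes, 3 rose and 4 fell, likewise adjusted over the list alone, and the list did not pass (camera adjusted p = 0.71, range 0.225 to 0.915, the ends without ESC-derived replicates 3 and 2). Ly6c2, expressed by monocytes and by memory T cells, rose by 2.57 ± 0.12. Of 10 megakaryocyte and platelet genes, 5 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 0.0054, lowest 0.00019, adjusted p = 0.168 with an estimated correlation). Of 13 erythroid genes, 2 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 0.03, lowest 0.00217 with fry, adjusted p = 0.205 with an estimated correlation). Car2, a carbonic anhydrase, fell from 987 ± 22.8 to 25 ± 15 CPM (-5.30 ± 0.48), and Hemgn was at least 145-fold lower. The erythroid call was lost with library totals only, with values divided by 4 and without LSK replicate 1 or ESC-derived replicate 1. Without ESC-derived replicates 2 or 3, 4 erythroid genes fell, and without ESC-derived replicates 1 or 3, 1 rose. The 4 embryonic globin genes, Hbb-bh1 and Hbb-y among them, had 0 counts in each of the 6 libraries. Of 10 mast cell, basophil and eosinophil genes, 4 fell and 2 rose, and adjusted over the list alone 4 fell and 3 rose, and the list did not pass (camera adjusted p = 0.26, range 0.0198 with fry to 0.505 with the replicate number as a block). Mcpt8, a basophil protease, averaged 58.3 ± 29.3 CPM in LSK cells and had 8 counts in ESC-derived cells, and Epx, an eosinophil peroxidase, had 0 counts in LSK cells and 43.7 ± 63.8 CPM in ESC-derived cells. ESC-derived replicate 2 held 4967 of the 5600 Epx counts, and the Epx call was lost with limma-voom and with no low-count filter. Without LSK replicate 3, 7 members of this list fell and its call passed.

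Genes of other tissues were low or mixed. Of 21 endothelial genes, 7 fell, 2 rose and 12 did not pass, and adjusted over the list alone 9 fell and 2 rose (camera adjusted p = 0.03, lowest 0.00181 with fry, adjusted p = 0.273 with an estimated correlation). Eng, a receptor also found on stem cells, fell by 4.94 ± 0.25 on the log2 scale. The endothelial call was lost with rank-based camera, with library totals only and without LSK replicate 3. Without LSK replicates 2 or 3, 4 members fell, and the rises numbered 1, 0 and 1 without LSK replicates 1, 2 and 3 and 1 without ESC-derived replicate 2. Of 14 stromal genes tested out of 26 listed, 2 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 0.042, lowest 0.00404 with fry, adjusted p = 0.279 with an estimated correlation), and the call was also lost with library totals only, with no low-count filter, with the stricter filter, with values divided by 4 and without LSK replicate 1, ESC-derived replicate 1 or ESC-derived replicate 2. Pdgfrb, a receptor of mesenchymal cells, averaged 27.1 ± 6.04 CPM in LSK cells and was at least 298-fold lower in ESC-derived cells, and the falls numbered 4 without ESC-derived replicate 3. Of 5 pluripotency genes tested out of 16 listed, 1 fell, Klf4 (-2.09 ± 0.49), likewise adjusted over the list alone, and the list did not pass (camera adjusted p = 0.72, range 0.0849 to 0.826). The median log2 fold change of the tested members was 2.48, and camera's direction was up. Klf4 is also expressed in mature myeloid cells, and its call was lost with the replicate number as a block and without any one of LSK replicates 1, 2 and 3, each leaving 0 falls. The rises in this list numbered 1 without LSK replicate 1 and 2 without LSK replicate 2. Of 8 fetal haematopoietic genes tested, 3 rose and 2 fell, likewise adjusted over the list alone, and the list did not pass (camera adjusted p = 0.18, range 0.00429 with fry to 0.686 with no low-count filter). Lgals1, a galectin also made by activated lymphocytes, rose by 4.42 ± 0.18, and Hmga2 averaged 8.29 ± 2.31 CPM in LSK cells and had 2 counts in ESC-derived cells. The fetal rises numbered 1 without any one of LSK replicates 1 and 2 and ESC-derived replicates 1 and 2, and 2 without ESC-derived replicate 3.

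Among cell programs, oxidative phosphorylation and G2/M genes shifted up and immediate early genes down at the preset correlation, and these 3 calls were lost with an estimated one. Of 30 oxidative phosphorylation genes, 20 rose and 0 fell, and adjusted over the list alone 21 rose and 1 fell (camera adjusted p = 7.6e-05, lowest 2.02e-08, adjusted p = 0.108 with an estimated correlation). Their median log2 fold change was 0.51, with Sdhb, a succinate dehydrogenase subunit, at 1.04 ± 0.11, and 11 and 13 members rose without LSK replicates 2 and 3. Of 30 G2/M genes, 9 rose and 2 fell, and adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 0.029, lowest 0.00309, adjusted p = 0.273 with an estimated correlation), and the call was also lost with library totals only. Cdc20, a mitotic activator, rose by 1.17 ± 0.11, and the G2/M falls numbered 1 without LSK replicate 2, LSK replicate 3 or ESC-derived replicate 2. Of 28 S phase genes, 8 fell and 3 rose, and adjusted over the list alone 9 fell and 3 rose, and the list did not pass (camera adjusted p = 0.18, range 0.00078 with fry to 0.273). The S phase list passed with fry and with no low-count filter. Mcm7, a replicative helicase subunit, fell by 0.86 ± 0.11 on the log2 scale, Ccne1, which encodes cyclin E1, rose by 1.94 ± 0.30, and 5 S phase genes fell without LSK replicate 2. Of 15 cell cycle inhibitors, 7 rose and 2 fell, likewise adjusted over the list alone, and the list did not pass (camera adjusted p = 0.14, range 0.00181 with fry to 0.273). It passed with fry and without ESC-derived replicate 3. Btg1 rose by 2.42 ± 0.10, Cdkn2b averaged 28.6 ± 7.01 CPM in ESC-derived cells and had 4 counts in LSK cells, and Cdkn1a fell by 3.34 ± 0.15 on the log2 scale. Of 24 immediate early and stress genes, 9 fell and 8 rose, and adjusted over the list alone 11 fell and 8 rose (camera adjusted p = 0.00039, lowest 3.33e-05, adjusted p = 0.133 with an estimated correlation, highest 0.302 with rank-based camera). The members Jun (-4.16 ± 0.11) and Nr4a1 (-3.13 ± 0.12), transcription factors induced within minutes of stimulation, fell and Klf2, a regulator of T cell quiescence, rose (1.54 ± 0.10). The immediate early call was also lost with rank-based camera, with the replicate number as a block and without LSK replicate 1, LSK replicate 3 or ESC-derived replicate 3. Of 36 interferon response genes, 11 rose and 6 fell, likewise adjusted over the list alone, and the list did not pass (camera adjusted p = 0.12, range 0.00371 with fry to 0.299). Ifi27l2a rose by 3.09 ± 0.21 and Ifitm3, also high in stem cells, fell by 3.02 ± 0.26 on the log2 scale, and the falls numbered 2, 2 and 3 without LSK replicates 1, 2 and 3. Of 22 NF-kB and TNF response genes, 7 rose and 4 fell, and adjusted over the list alone 7 rose and 5 fell, and the list did not pass (camera adjusted p = 0.26, range 0.000773 with fry to 0.392 with library totals only). Tnfaip3, an inhibitor of NF-kB signalling, rose by 1.58 ± 0.13, and Ccl3, a chemokine, fell by 2.61 ± 0.21 on the log2 scale. Of 19 glycolysis genes, 6 rose and 4 fell, and adjusted over the list alone 6 rose and 6 fell, and the list did not pass (camera adjusted p = 0.43, range 0.00109 with fry to 0.999 with rank-based camera). The glycolysis median and mean were negative (-0.20 and -0.03) where camera's direction was up. Pfkp rose by 2.87 ± 0.18 and Hk2 fell by 2.05 ± 0.28 on the log2 scale. Of 26 ribosome biogenesis and Myc target genes, 7 fell and 2 rose, and adjusted over the list alone 9 fell and 2 rose, and the list did not pass (camera adjusted p = 0.26, range 0.00356 with fry to 0.359 without ESC-derived replicate 2). Gnl3, a nucleolar GTPase, fell by 0.94 ± 0.18 on the log2 scale. The ribosome biogenesis falls numbered 2, 3 and 3 without LSK replicate 2, LSK replicate 3 and ESC-derived replicate 3, and the rises 1, 0, 0 and 1 without LSK replicates 1, 2 and 3 and ESC-derived replicate 1.

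**Figure D2:**
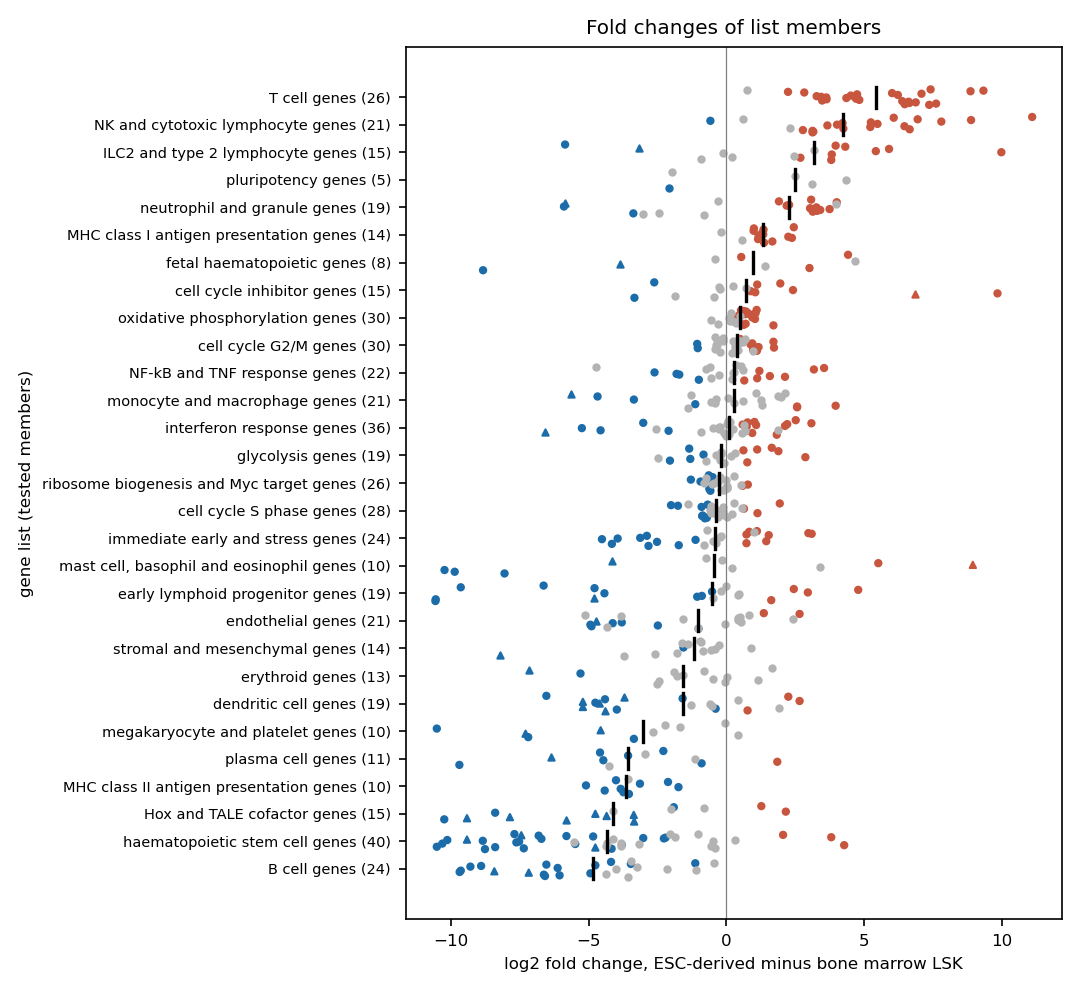
Log2 fold changes of tested members of 29 gene lists, ESC-derived minus LSK, with red points for members that rose, blue for members that fell, grey for members that did not pass, triangles for members at 0 in a group drawn at their bound, and black bars for list medians with those members at their bound. The T cell list has a median of 5.43 and the B cell list a median of -4.85.

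The 8 largest rises under the rule were Samd3, Gzmk, Ccl1, Klrg1, Ifngas1, Zfp683, Cd8b1 and Sh2d1a. Klrg1, an inhibitory receptor of effector lymphocytes, rose by 9.99 ± 0.46 (10.77 without LSK replicate 3), Cd8b1, the second chain of the CD8 co-receptor, by 9.34 ± 0.32 to 2128 ± 174 CPM, and Sh2d1a, a signalling adaptor of T and NK cells, by 9.30 ± 0.47, with 26.6% of its exonic bases shared with Tenm1 on the opposite strand. Gzmk, a granzyme, averaged 108 ± 8.46 CPM in ESC-derived cells and had 7 counts in LSK cells, and Zfp683, a transcription factor of tissue-resident T cells, averaged 60.7 ± 17.6 CPM against 9 counts. The 8 largest falls were Tsix, Hoxa9, Nkx2-3, Shisa8, Afap1l1, Nmral1, Flt3 and Dntt. Tsix, the antisense partner of Xist on the X chromosome, averaged 781 ± 308 CPM in LSK cells and 0 in ESC-derived cells, at least 8554-fold lower, and Xist averaged 443 ± 277 and 2.29 ± 2.52 CPM (-7.58 ± 1.28, and -8.92 without ESC-derived replicate 3). Tsix and Xist share 1980 exonic bases on opposite strands, 32.6% of those of Tsix and 11% of those of Xist, and reads in that stretch cannot be assigned to one of them. In LSK replicates 1 to 3 Tsix held 665, 548 and 1131 CPM and Xist 572, 633 and 125 CPM. Their sum was steadier, at 1240, 1180 and 1260 CPM. The division between the genes, and so the level and SD of each alone, is therefore uncertain. Xist lost its call with limma-voom, where its adjusted p was 0.0725, the highest of a range that began at 3.99e-08. The Y-linked genes Ddx3y (1.76 ± 0.505 and 2.18 ± 0.282 CPM in ESC-derived and LSK cells), Eif2s3y, Kdm5d and Uty averaged under 3 CPM in both groups and did not pass, and Xist was the 1 sex-linked gene of 5 that fell, likewise adjusted over the list alone. The ESC-derived libraries had 12419 ± 99 genes at 1 CPM or more and the LSK libraries 13861 ± 215, a difference of -1442 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow).

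The groups differed at once in cell origin, transplantation and c-Kit gate, so a difference cannot be assigned to any of these, and as the labels do not name separate animals, p-values measure only the spread between these libraries, which may be technical. Pearson correlations of log2 CPM were 0.96 to 0.984 within LSK, 0.959 to 0.966 within ESC-derived and 0.862 to 0.877 between groups, across genes, which are not independent replicates. Of the tested genes, 49.8% had no overlap between groups, against 10% by chance. LSK replicate 2 lay between LSK replicates 1 and 3 for 68.4% of 6391 genes with a mean of at least 20 CPM, against 33.3% by chance and 28.4 to 37.6% for the ESC-derived libraries. Over 452 genes at 0 in one of LSK replicates 1 and 3 and at 2 CPM or more in the other, LSK replicate 2 had a median level of 45.1% of the library with the gene (quartiles 32.7 and 59.0%) and was at 0 for 2.2%. In the ESC-derived libraries the share at 0 over such genes was 40.7 to 44.7%. Of 118 named genes past the threshold, 105 passed without LSK replicate 2, and all 29 lists kept their side of the threshold. With library totals only, in place of TMM, 1756 genes were higher and 3057 lower, and the median log2 fold change of all genes moved by -0.25. No named gene or list that passed changed direction under any scaling.

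**Figure D3:**
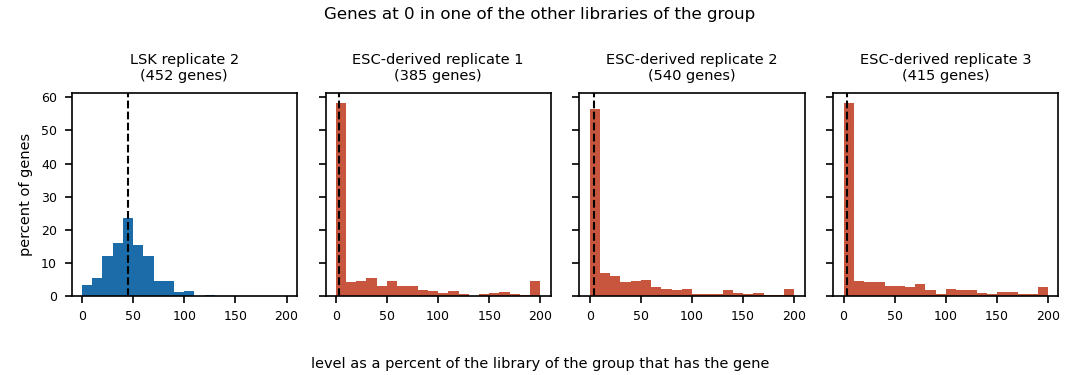
Level of a library, as a percent of the level in the library of its group that has the gene, over genes at 0 in the remaining library, in bins of 10 percentage points with values of 190 or more in the last bin and dashed lines at the median. LSK replicate 2 centres on 45.1% over 452 genes, while 40.7 to 44.7% of the genes are at 0 in the ESC-derived libraries.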

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

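Division of the values by 4 and the fits without immunoglobulin or lymphocyte genes were chosen after seeing the data, and the other alternatives before. The count of genes that differed, 4861, stayed within 1.5 times under the DESeq2 Wald test (6299), limma-voom (5779), the scalings, the filters, thinning and the added settings. Against a 2-fold change 2354 genes passed, 971 higher and 1383 lower, fewer by the test's construction. Deviations from the group mean correlated at 0.004, 0.054 and 0.006 between libraries with the same replicate number, across genes. Between libraries with different numbers the values ran from -0.044 to 0.022. The numbers thus showed no strong pairing, and with 3 libraries per group a shared day or batch is not excluded. With the replicate block 3220 genes differed, 1488 of them lower, and the cause was not tested. Leaving out a library gave 2716 to 4603 genes, 1466 to 2163 higher and 1250 to 2440 lower, the low ends without LSK replicate 2, and 15 to 19 lists against 18. With an estimated correlation 7 lists passed, those of stem cell, Hox, B cell, T cell, NK, ILC2 and MHC class I genes. A higher correlation is not the whole reason. The dendritic cell list was estimated at -0.03, under the preset 0.01, and its camera adjusted p still went from 0.044 to 0.168. The T cell list, also at -0.03, went from 1.3e-98 to 0.000527. The other lists that lost their call had estimates above the preset. In limma's camera, the test with an estimated correlation also uses the 4 residual degrees of freedom. The test with a preset correlation uses a number set by the genes in the fit. Very low p-values at the preset correlation thus rest on the number of genes as well as on the libraries. How much each difference contributed was not measured. Fry, which compares no list with other genes, called 27. The difference in detected genes, -1442, was -990 with at least 1 count (exact permutation p = 0.2; the cause was not tested) and -1512 to -1318 with a library left out. For named genes 2263 alternative values kept their side of the threshold, 80 lost the call and 6 gained it. For lists the numbers were 474, 34 and 14. No value that passed in the main fit or in the alternative reversed direction. Direction was not scored where neither passed, and Eif2s3y ranged from -0.45 to 0.41. With about 4 counts per fragment, totals of a few counts rest on 1 to 3 fragments. The 10 splits of the 6 libraries are too few for a share under 0.05. In 1 of the 10, the real one, edgeR called 4861 genes (2395 higher, 2466 lower), and in the other 9 at most 0, with at most 250 at an unadjusted p of 0.05 and at most 86 by DESeq2. Camera called 18 lists in the real split and 7 to 11 in the others. Each other split has libraries of both groups on each side, so the group difference widens the spread and leaves little to call. These splits also keep part of the group contrast, so their calls do not give a rate of false calls.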

Other observations

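The genes and tests below were chosen after their values were seen. Ifng, the interferon made by T and NK cells, averaged 571 ± 80.6 CPM in ESC-derived cells and 3.55 ± 0.928 CPM in LSK cells (log2 fold change 7.33 ± 0.26), with 25.9% of its exonic bases shared with Gm49751. The chemokine receptors Cxcr3 (7.17 ± 0.16) and Cxcr6 (8.39 ± 0.36), the inhibitory receptors Pdcd1 (6.40 ± 0.35), Cd160 (6.77 ± 0.18) and Lag3 (1.81 ± 0.22), and the transcription factors Tbx21 (6.47 ± 0.29), Eomes (5.23 ± 0.32) and Tox (2.80 ± 0.18) rose. Cd44, an activation marker that progenitors also carry, averaged 87.4 ± 3.94 and 84.3 ± 16.9 CPM and did not pass (edgeR adjusted p = 0.86). Tcf7 (4.36 ± 0.21) and S1pr1 (1.55 ± 0.15), which naive T cells also express, rose, and Ccr7, likewise a gene of naive T cells, did not pass (0.46 ± 0.24, edgeR adjusted p = 0.2). No list of T cell states was tested. The receptor gamma constant genes Tcrg-C2 and Tcrg-C4 averaged 631 ± 5.22 and 423 ± 47.2 CPM in ESC-derived cells and 1.46 ± 0.463 and 2.32 ± 1.49 CPM in LSK cells. The delta constant gene Trdc rose as well, from 0.624 ± 0.22 to 7 ± 2.53 CPM (3.48 ± 0.63). It stayed far below the alpha and beta constant genes Trac and Trbc1 of the planned T cell list. These averaged 1002 ± 102 and 1201 ± 151 CPM in ESC-derived cells.

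The library labelled LSK replicate 2 lay close to a mixture of LSK replicates 1 and 3. Its mean absolute log2 difference from the nearest mixture was 0.117, against 0.312 to 0.352 for each ESC-derived library and the mixtures of the other two. For LSK replicates 1 and 3 the differences were 0.226 and 0.254, and in both the nearest mixture was LSK replicate 2 alone. The distances between kappa V usages were 15.9 percentage points from replicate 1 to 2, 12.9 from 2 to 3 and 28.9 from 1 to 3. Independent libraries that each sample rare transcripts are argued against by the 2.2% of genes at 0 in LSK replicate 2, where the ESC-derived libraries gave 40.7 to 44.7%. A gradient that scales each gene was examined over the 223 genes at least 8-fold apart. There LSK replicate 2 sat 79.4% of the way up on the log scale (quartiles 70.0 and 84.9%). The medians of the ESC-derived libraries, 67.7 to 74.8%, were not far from that, with wider quartiles. A high place thus also arose in libraries farther from a mixture, so this measure cannot decide against a gradient. The median of 45.1% of the library with the gene, over genes at 0 in the other, is consistent with about equal parts of cells, RNA, cDNA or reads of replicates 1 and 3, and nothing here tells these stages apart. No biological explanation was tested, and if the mixture holds, the LSK group has fewer than 3 independent samples.

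Immunoglobulin transcripts were abundant in the LSK libraries, with Igkc at 30787 ± 5608 CPM, Igkv1-135 at 9679 ± 3544 CPM and Igha at 3818 ± 405 CPM. Transcription of unrearranged loci in lymphoid-primed progenitors, as the whole source, is argued against by V segments, which held at least 35.4% of the immunoglobulin counts in each LSK library. Class-switched constant genes reached at least 31.9% of the Ighm counts, which is consistent with antibody-secreting cells or their RNA in the LSK libraries. Of the 11 plasma cell genes of the planned list, none of which is in another list, 8 were lower in ESC-derived cells, and the most abundant in LSK cells were Jchain (4289 CPM), Mzb1 (143 CPM) and Xbp1 (129 CPM). A lineage gate with B cell antibodies would remove B cells, and the c-Kit and Sca-1 gates would remove plasma cells without these antigens, so how such RNA entered stays open.

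The 3 ESC-derived libraries used nearly the same T cell receptor beta V segments, with Trbv5 at 37.5, 37.4 and 38.5%, Trbv19 at 30.2, 30.1 and 27.1% and Trbv31 at 16.3, 18.0 and 17.1% of V counts. The largest distance between any 2 of them was 5.4 percentage points for beta V segments, 5.7 for gamma V segments and 20.5 for alpha V segments, where the smallest alpha V distance within the LSK libraries, over 317 to 361 counts each, was 41.8 and between groups 69.5. A broad usage that any T cells of the strain would share is argued against by the 3 most used segments, which held at least 82.7% in each library, while the 3 most used of each LSK library held 35.3 to 39.4% of 315 to 459 V counts. One animal, one pool of cells or the same expanded clones behind the 3 libraries may account for the beta V usage, although a lineage gate against CD3, CD4, CD5 or CD8 would remove T cells, and cell origin and transplantation stay open as untested. Whether few clones are present cannot be told apart from the alpha V segments, of which the 3 most used held at most 25.5%, a share between the bounds set for few and for many clones.

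Other values stand without explanation. Xist and Tsix together held 1240, 1180 and 1260 CPM in LSK replicates 1 to 3 and 1.71, 0.118 and 5.05 CPM in ESC-derived replicates 1 to 3. The eosinophil genes Epx (4.19, 117 and 9.65 CPM) and Prg2 (50.6, 1139 and 136 CPM) were highest in ESC-derived replicate 2. The myeloid granule gene Mpo held 127, 116 and 3.82 CPM in the ESC-derived libraries. The kappa V usage of ESC-derived replicate 3, over 2507 counts, lay 14.9 to 22.3 percentage points from those of the LSK libraries, against 91.9 and 95.3 points from ESC-derived replicates 2 and 1. The transcript CT010467.1, which overlaps Gm42418 and AY036118, held 1.04 to 1.28% of counts in the LSK libraries and 0.193 to 0.324% in the ESC-derived libraries, and mitochondrial transcripts 2.57 to 2.90% and 1.62 to 2.23%.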
